A study of Mus musculus with 5 samples.

How the data were processed

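Colon RNA from 5 libraries of the AOM and DSS mouse model was analysed, with 1 library at each of W0, W2, W5, W8 and W11. Total RNA was taken with TRIzol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. FastQC, HISAT2 2.2.1 and featureCounts are named per the submitters' processing notes, which name GRCm38 as well as GRCm39, so no coordinates are printed. The role of each tool, the annotation release, the strand setting, the treatment of multi-mapped reads and the pooling of mice are not given in the sources used here.

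The deposited table holds 2 columns per library. The columns headed TPM hold whole-number read counts as deposited by the authors, since their values are whole and sum to a different total in each library. The columns headed count hold RPKM-like values, that is, deposited counts divided by a gene length and a library denominator. Their sums differ between libraries, which sums of TPM do not. The ratio of the first kind of column to the second was taken relative to W0. It was the same within 1% in all 2620 genes with more than 5 RPKM in each library. The kinds are thus rescaled forms of each other, which does not show which is which. From the whole numbers and the differing sums, the headers were taken to be exchanged. The analysis had been planned for TPM, with CPM (counts per 1000000 counted reads) as the stated choice if the table held counts, and that choice was used. With gene lengths of 11 mitochondrial genes, the gene counts came to between 46.2% and 50.9% of the library denominators that the RPKM values imply.

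Counts were divided by the library total and multiplied by 1000000 to give CPM, and folds were taken as differences of log2(CPM + 1), which understates the change of low genes. Genes with a mean CPM of at least 1 over the 5 libraries were kept (14720 of 52382). A symbol carried by several identifiers was given to the one with the highest total, and 118 identifiers had no symbol. A gene was called changed at 2-fold or more. With 1 library per time point there is no test across conditions and no p-value. Ratios have exact conditional (Clopper-Pearson) 95% intervals from the counts, and a library at 0 was set to a floor of 3 counts, between 0.147 and 0.224 CPM, to give a lower bound on a fold. Intervals and floors cover counting error only. All genes called changed had counting intervals that excluded a ratio of 1, which says nothing about changes missed at few counts.

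The gene lists, the rules and the first set of alternatives were fixed before the data were examined. Each of 42 lists with at least 3 tested members was summarised by its median log2 fold, and placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart when it lies outside the central 95%, which describes these libraries and is not a p-value. Named genes are Zg16, the 6 largest rises and 6 largest falls in each comparison, up to 4 members per list with the largest folds and at least 1 CPM in either library, and the 10 genes per direction with the largest smallest-fold at W5, W8 and W11. Clone-named loci, pseudogenes, immunoglobulin and T cell receptor segments, and ribosomal, Y-linked and mitochondrial genes were left out of the largest changes. Genes named outside this rule are marked as chosen after their values were seen.

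Gene length was taken relative to other genes from the ratio of the deposited columns, and GC content from the longest transcript of each gene in GENCODE M21, which held 99.4% of the identifiers. The overlap of genes was taken from the same annotation, by identifier. The calling and list steps were tested on simulated counts with known folds and counting error only. Differences between mice or preparations were left out, so the false calls given are those of counting error alone. Among 100 genes each, 3-fold changes were called in 92 (W2), 87 (W5), 91 (W8) and 90 (W11), 4-fold changes in 94, 92, 95 and 94, and of the unchanged genes 1 was called at W8 and 0 in the other comparisons. Of 100 unchanged lists of randomly drawn genes, 5 (W2), 4 (W5), 5 (W8) and 4 (W11) fell outside the central range.

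Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 CPM, median-of-ratios scaling over genes with a mean of at least 10 CPM, totals without mitochondrial, immunoglobulin and hemoglobin genes and the 50 genes with the highest mean, and the mean of W0 and W2 as the baseline. The deposited RPKM values, removal of the length or GC trend, W2 as the baseline, and leaving out a time point were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Several genes that colon tissue uses are listed at 0 in all libraries, and reads of close paralogs can be shared, so a value of 0 in all libraries is not read as absence.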

Results

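The data are RNA sequencing libraries of mouse colon from a time series of colitis-associated colon cancer. In this model the mutagen azoxymethane (AOM) is injected, and dextran sulfate sodium (DSS), which injures the colonic epithelium, is then given in the drinking water in cycles. The labels describe male C57BL/6 wild-type mice, AOM at 8.5 mg per kg and DSS at 1.5%. There are 5 libraries: an untreated control (W0), a library labelled as AOM alone (W2), and 3 libraries labelled as AOM and DSS (W5, W8 and W11), each named for its week. The control is described both as taken before administration and as killed at the same time as the treated mice, so whether the folds against W0 also include a difference in age is not known. Each time point has 1 library. The labels name both colon tissue and intestinal epithelial cells. The W0 library held the smooth muscle gene Acta2 at 1014 CPM and the B cell gene Cd79b at 35.1 CPM, so it was not of epithelial cells alone. Shifts of cell type lists can thus also come from the tissue sampled. From each group 3 mice were selected, without a statement on pooling. No difference between time points below therefore has a replicate check, and "rose", "fell" and "changed" are used only for a fold of at least 2 between a pair of libraries. The libraries held 13778653 (W0), 14640851 (W2), 20379429 (W5), 13389184 (W8) and 14945610 (W11) counted reads, and between 20111 and 21245 genes were detected in each.

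The series title concerns Zg16, a lectin-like protein secreted by goblet cells into the colonic mucus. Zg16 (ENSMUSG00000049350) was measured at 3818 CPM (counts per 1000000 counted reads) at W0, 2691 at W2, 1319 at W5, 630 at W8 and 291 at W11. It was thus lower in each later library than in the one before. Its log2 fold against W0 was -0.50 at W2, which is under the 2-fold criterion, and it fell by 1.53 at W5, 2.60 at W8 and 3.71 at W11. On the CPM scale the W11 value was 13.1-fold lower than the W0 value, with a 95% interval of 12.7 to 13.5 that covers counting error only. The fall at W5, W8 and W11 stayed over 2-fold under every alternative tried, including W2 as the baseline.

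**Figure D1:**
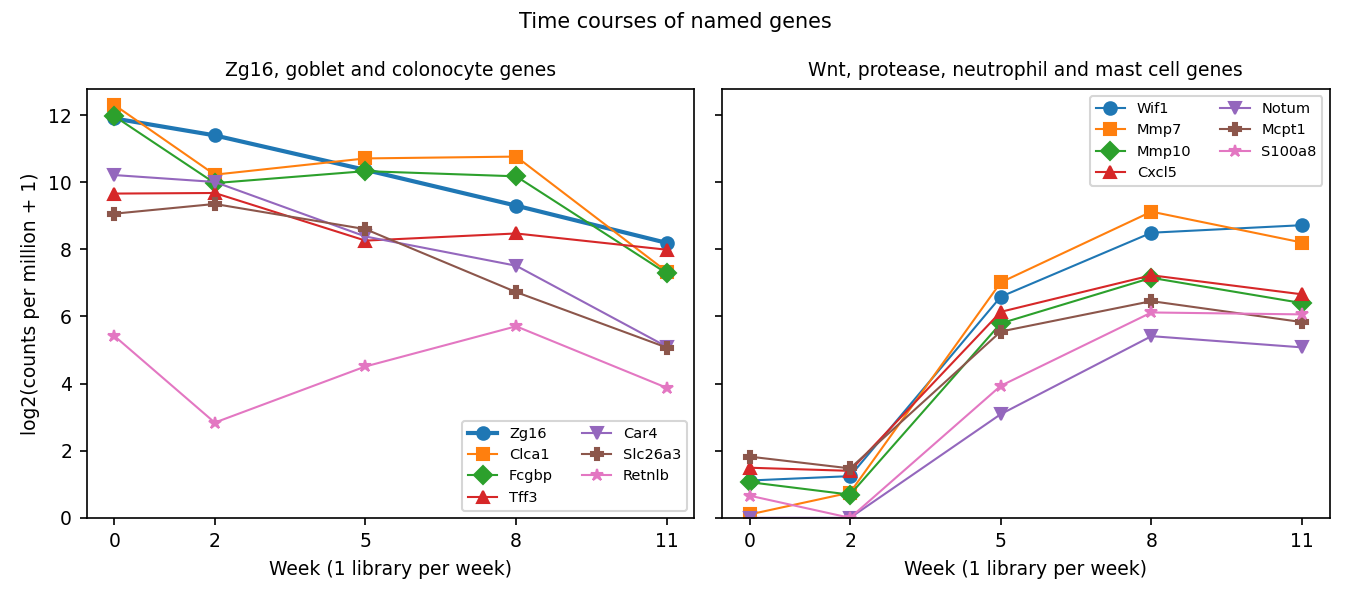
Expression by week, as log2(CPM + 1), in the 5 libraries (1 library per week, no error bars). The left panel plots Zg16 and other goblet and colonocyte genes, with Zg16 falling from 3818 to 291 CPM. The right panel plots genes of Wnt signalling, proteolysis, neutrophils and mast cells, with Wif1 at 1.16 CPM at W0 and 420 CPM at W11.

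Across the 14720 genes tested, the W0 library was closest to W2 (Pearson r = 0.96 across genes) and W5 (r = 0.96), followed by W8 (r = 0.93) and W11 (r = 0.88). Genes are not independent replicates, so these correlations describe the libraries only. Genes at least 2-fold higher than at W0 numbered 502 at W2, 976 at W5, 1146 at W8 and 1662 at W11, and genes at least 2-fold lower numbered 623, 275, 567 and 2484. The median log2 fold of all genes was -0.02 at W2, 0.11 at W5, 0.11 at W8 and -0.15 at W11. With folds centred on that median the counts of higher and lower genes were 544 and 591 at W2, 763 and 407 at W5, 963 and 752 at W8, and 2077 and 1876 at W11. Centring moved the share of higher genes among the changed ones from 78.0% to 65.2% at W5, from 66.9% to 56.2% at W8, and from 40.1% to 52.5% at W11, so the balance of directions at these time points depends on the scaling.

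**Figure D2:**
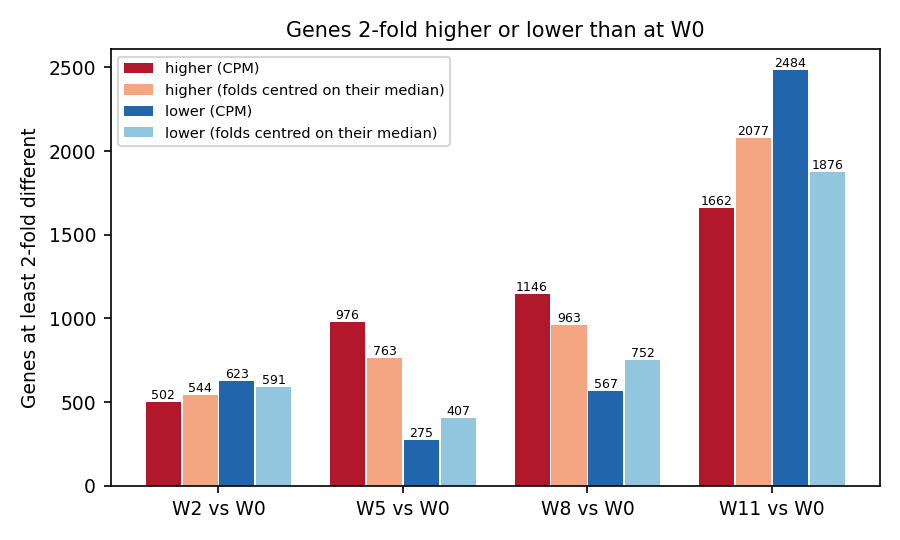
Number of genes at least 2-fold higher (red) or lower (blue) than at W0 in each comparison of 1 library with 1 library. Dark bars use CPM and pale bars use folds centred on the median of all genes, which turns the W11 balance from 1662 higher and 2484 lower to 2077 and 1876.

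The comparison of W2 with W0 addresses the colon after AOM and before the DSS cycles. Interferon response genes were higher: 8 of 16 measured members rose, none fell, and the list median of 1.04 lay above all 10000 matched random lists. Iigp1, an interferon-inducible GTPase, rose from 20.1 to 139 CPM (log2 2.73), Gbp2 by 1.68 and Isg15 by 1.67. Ido1, the interferon-induced tryptophan-degrading enzyme, rose from 2.98 to 22.7 CPM (log2 2.57), and Il18bp, an inhibitor of interleukin 18, rose by 2.44. None of the 7 MHC class II genes passed the 2-fold criterion, but 6 were above W0 and the list median of 0.85 lay at percentile 99.99 of random lists, with Cd74 at 0.85 and H2-DMa at 0.91. The antimicrobial list stood below random lists (median -0.44, percentile 0.47), with 3 of 14 lower. In it Ang4, a microbicidal ribonuclease, fell from 131 to 3.89 CPM (log2 -4.76), Retnlb, a goblet cell antibacterial protein, fell by 2.58, and Reg3b, a C-type lectin, was at 2.32 CPM at W0 and 0 at W2, at least 11.3-fold lower.

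Goblet genes also stood below random lists at W2 (median -0.49, percentile 0.06), with 5 of 16 lower and no member higher. Clca1, a secreted mucus protein, fell from 5053 to 1195 CPM (log2 -2.08), and Fcgbp, another mucus component, fell by 1.99. Proliferation genes stood above all random lists (median 0.73), with 22 of 23 above W0 and 2 past the 2-fold criterion, Ube2c at 1.42 and Cdc20 at 1.20. The mitochondrial-encoded list (median 1.41, 9 of 12 higher and 1 lower) and enteric neuron and glia genes (median 1.25, 6 of 9 higher) lay above all random lists, with Nos1, the neuronal nitric oxide synthase, at 1.56. Smooth muscle genes stood above random lists as well (median 0.47, 1 of 10 higher), where Tagln, an actin-binding protein of smooth muscle, rose by 1.60. Fibroblast and matrix genes (median -0.65, 3 of 16 lower), endothelial genes (median -0.67, 2 of 10 lower) and macrophage genes (median -0.44, 3 of 14 lower) stood below random lists, with Mmp2 at -1.26, Kdr at -1.05 and Csf1r, the receptor for macrophage colony-stimulating factor, at -1.32. Among lymphoid lists, T cell (median 0.61, 1 of 12 higher) and B cell genes (median 0.52, 1 of 9 higher) stood above random lists and plasma cell genes (median -0.57, 1 of 7 lower) below, with Cd79b at 1.01 and Jchain, the joining chain of IgA and IgM, at -1.03.

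Among single genes at W2, Col19a1, a minor collagen, rose from 1.60 to 26.0 CPM (log2 3.38), and Sspn, a member of the dystrophin complex, rose from 317 to 1798 CPM (log2 2.50). Mptx2 fell by 3.11, although its reads can be shared with close paralogs, and Pcsk6, a proprotein convertase, fell by 2.44. The clock-controlled genes that peak with Dbp stood below all random lists (median -1.08, 4 of 6 lower), with Nr1d1 at -1.66. At W2, 11 lists stood above and 11 below random lists, of 42, where 2.1 outside would be given by lists of unrelated genes. Genes of a list can vary together between libraries, which random lists matched on expression alone leave out. Some lists also share members, such as Zg16 in the goblet and antimicrobial lists, so the lists are not independent of each other. More lists than that can thus stand apart without an effect of treatment. Mitochondrial-encoded genes held 4.87% of counts at W2 and 2.19% at W0, and with a pseudocount of 5 the numbers of higher and lower genes were 169 and 324.

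The comparison of W5 with W0 addresses the colon after DSS exposure has begun. Matrix remodelling genes showed the largest list median, 3.23, with 7 of 10 higher, above all random lists. Mmp7, a matrix metalloproteinase and Wnt target, was at 0.0726 CPM (1 count) at W0 and 128 CPM at W5, a ratio of 1767 with a counting interval of 317 to 69833. Mmp10 rose from 1.09 to 54.5 CPM (log2 4.73), Mmp3 by 3.68 and Mmp9, the neutrophil gelatinase, by 3.36. Wnt target genes stood above all random lists (median 1.14, 12 of 20 higher, none lower). Wif1, a secreted Wnt inhibitor, rose from 1.16 to 95.1 CPM (log2 5.48), Prox1, a homeobox transcription factor, by 3.59 and the stem cell receptor Lgr5 by 2.10. Notum, a secreted Wnt deacylase, was at 0 at W0 and 7.51 CPM at W5, at least 34.5-fold higher.

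Inflammatory lists stood above random lists at W5. Inflammatory cytokines had 8 of 15 members higher (median 1.33), with Cxcl5, a neutrophil chemoattractant, rising from 1.81 to 69.4 CPM (log2 4.64), Nos2, the inducible nitric oxide synthase, by 2.72 and Il1b by 2.03. Neutrophil genes had 8 of 9 higher (median 1.25, or 1.60 with genes at 0 set to their bound), including S100a8 at 3.27 and S100a9 at 3.36. Mast cell genes had 6 of 8 higher (median 1.73, or 2.02 at the bounds), where the mucosal proteases Mcpt1 and Mcpt2, which can share reads, rose by 3.73 and 4.53. Macrophage genes (median 0.61, 3 of 14 higher) included Arg1, an arginine-degrading enzyme, which rose from 0.726 to 24.5 CPM (log2 3.88). Antimicrobial genes, which stood below random lists at W2, stood above random lists at W5 (median 0.90, 7 of 14 higher and 1 lower), with Lcn2, an iron-sequestering protein, at 3.49 and Saa3, an acute phase protein, rising from 2.03 to 108 CPM (log2 5.16). Interferon response genes were also above W0 (median 0.98, 7 of 16 higher), but their median was 0.028 against W2, inside the random range, and the fold of Iigp1 was 2.18 against W0 and -0.56 against W2. Plasma cell genes (median 0.57, 2 of 7 higher) included Jchain, which rose from 1223 to 4394 CPM (log2 1.84). T cell genes stood above random lists (median 0.76, 3 of 12 higher, percentile 99.75), and so under 6 of the 7 settings chosen beforehand. B cell genes stood below random lists (median -0.25, percentile 2.11) with 1 of 9 higher and none lower, and their median was 0.15 with the deposited RPKM values.

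Of the epithelial lists at W5, absorptive colonocyte genes lay below all random lists (median -0.49, 4 of 20 lower), with Car4, a membrane carbonic anhydrase, falling from 1186 to 333 CPM (log2 -1.83). Posterior Hox genes, which mark position along the gut, also stood below (median -0.47, percentile 0.78, and so under 6 of the 7 settings chosen beforehand), with none of 6 past the 2-fold criterion. Goblet genes had 4 of 16 lower (median -0.31, percentile 1.10), namely Zg16, Clca1, Fcgbp and Tff3, the trefoil peptide, at -1.40. With W2 as the baseline the goblet median at W5 was 0.46, above random lists, and that at W8 was 0.20, inside the random range, and Clca1 and Fcgbp lay above their W2 levels at both time points. Stem and progenitor genes (median 0.55, 3 of 14 higher) and the fetal and regenerative list (median 0.65, 2 of 10 higher and 1 lower) stood above random lists, but against W2 their medians were 0.32 and -0.026, inside the random range. The fetal and regenerative list held Spp1, which rose from 1.02 to 24.9 CPM (log2 3.68). General epithelial genes had a median of -0.38 at W5, inside the random range. Proliferation genes stood above random lists at W5 (median 0.34, 1 of 23 higher), but their median was -0.036 against the mean of W0 and W2, inside the random range, and -0.33 against W2, below random lists. The mitochondrial-encoded list (median 0.65, 3 of 12 higher) also stood above, but its median was -0.069 against the mean of W0 and W2, inside the random range, and -0.79 against W2, below random lists. H19, an imprinted long non-coding RNA, was at 0 at W0 and 87.9 CPM at W5, at least 404-fold higher. Igf2bp3, an oncofetal RNA-binding protein, fell from 36.9 to 2.99 CPM (log2 -3.25) and Sstr1, a somatostatin receptor, fell by 2.37. Immediate early genes lay below all random lists at W5 (median -1.08, 7 of 12 lower), with Hspa1a, a heat shock protein, at -1.46 and Fos at -1.28. The clock genes that peak with Bmal1 stood below as well (median -0.69, percentile 0.10, 2 of 4 lower), with Npas2 at -1.42 and Arntl, the gene of Bmal1, at -1.01.

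At W5, 18 lists stood above and 6 below random lists. Folds at W5 followed transcript GC content (Spearman rho across genes -0.37), with medians of 0.45 in the lowest and -0.21 in the highest decile. With a pseudocount of 5 the numbers of higher and lower genes were 447 and 128, and under median-of-ratios scaling 416 genes were lower.

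The comparison of W8 with W0 addresses a later week of the AOM and DSS model. Wnt target, stem cell, matrix, neutrophil and cytokine lists had larger medians than at W5, all above random lists. Wnt target genes had 15 of 20 members higher and none lower (median 2.36), with Wif1 at 360 CPM (log2 7.38), Apcdd1, a Wnt inhibitor, rising from 2.32 to 129 CPM (log2 5.29) and Notum at least 191-fold higher. Stem and progenitor genes had 7 of 14 higher (median 1.09), including Lgr5, which rose from 5.66 to 65.1 CPM (log2 3.31), Tnfrsf19 by 3.35 and Axin2, a feedback inhibitor of Wnt signalling, by 1.88. Matrix remodelling genes had 7 of 10 higher (median 3.97), with Mmp7 at 556 CPM, a ratio to W0 of 7664 with a counting interval of 1375 to 302737, and Mmp13 at 4.81. Proliferation genes were all above W0 (median 0.61), 3 of 23 past the 2-fold criterion, but their median was 0.26 against the mean of W0 and W2 and 0.017 against W2, both inside the random range.

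Neutrophil genes (median 2.75, or 3.57 at the bounds, 8 of 9 higher) included S100a9, from 0.435 to 102 CPM (log2 6.16). Inflammatory cytokines had 10 of 15 higher (median 1.58), with Cxcl5 at 149 CPM (log2 5.73), Nos2 at 3.70 and Il23a at 7.24 CPM against 1 count at W0, a ratio of 99.8 with a counting interval of 17.5 to 3983. Antimicrobial genes had 8 of 14 higher and 2 lower (median 1.69, above all random lists), with the lectins Reg3b at 420 CPM (log2 6.98) and Reg3g at 256 CPM against 2 counts at W0, a ratio of 1762 with a counting interval of 487 to 14554. These paralogs can share reads, as can Itln1, an intelectin, which rose from 4.86 to 359 CPM (log2 5.94). Defa24, a Paneth cell alpha-defensin with near-identical copies, was at 0 at W0 and 614 CPM at W8, at least 2819-fold higher. Mast cell genes (median 2.25, or 2.41 at the bounds, 6 of 8 higher) and plasma cell genes (median 0.89, 1 of 7 higher) stood above random lists, while B cell genes lay below all of them (median -1.17, 6 of 9 lower), with Pax5, the B cell transcription factor, at -1.92. Arg1 was at 108 CPM (log2 5.98).

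Absorptive colonocyte, goblet, enteroendocrine and xenobiotic metabolism genes stood below random lists at W8, while tuft cell genes (median -0.17, 1 of 7 higher and 1 lower) and tight junction genes (median -0.091, 1 of 15 higher and 1 lower) lay inside the random range. Absorptive colonocyte genes had 13 of 20 lower and 1 higher (median -1.15), with the water channel Aqp8 falling from 254 to 37.8 CPM (log2 -2.72), the magnesium channel Trpm6 by 2.90 and Car4 by 2.70. Posterior Hox genes stood below random lists here too (median -0.73, percentile 0.24), with 1 of 6 lower, namely Hoxd11 at -1.13. Goblet genes had 5 of 16 lower and 1 higher (median -0.52, percentile 0.01), enteroendocrine genes 5 of 8 lower (median -1.20), among them the insulin-like peptide Insl5 (log2 -1.33), and xenobiotic metabolism genes 7 of 11 lower (median -1.56), among them Cyp2c55 (log2 -2.88) and the sulfotransferase Sult1a1 (log2 -2.14). General epithelial genes stood below random lists (median -0.45, percentile 0.43) with 1 of 12 higher, namely Cldn4, a claudin, which rose from 13.2 to 291 CPM (log2 4.36), and against W2 their median was -0.099, inside the random range. Squamous epithelium genes had 5 of 6 higher (median 2.09, or 2.14 at the bounds, above random lists), with Krt14, a basal keratin, at 3.47. Adipocyte genes had 3 of 5 lower (median -1.27, percentile 0.06, and -0.42 inside the random range at a mean of at least 5 CPM), with Adipoq, the fat cell hormone adiponectin, at 3.56 CPM at W0 and 0 at W8, at least 15.9-fold lower, and Cfd, adipsin, was 94.3-fold lower with a counting interval of 25.7 to 784 on 2 counts at W8. Smooth muscle genes stood below random lists (median -0.52, 2 of 10 lower), with Myh11, the smooth muscle myosin, at -1.17. Immediate early genes had 8 of 12 lower (median -1.43, below all random lists), with Fosb at -2.72, and the clock genes that peak with Bmal1 had 1 of 4 lower (median -0.77, percentile 0.070), namely Arntl at -1.23. At W8, 14 lists stood above and 14 below random lists, and with a pseudocount of 5 the numbers of higher and lower genes were 652 and 277. The interferon list stood above random lists at W8 (median 0.47, 3 of 16 higher) but below them against the mean of W0 and W2 (median -0.14) and against W2 (median -0.67), and the MHC class II list stood below (median -0.42, none of 7 past the 2-fold criterion) under 5 of the 7 settings chosen beforehand.

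The comparison of W11 with W0 addresses the last time point. Car4 fell from 1186 to 33.3 CPM (log2 -5.11), Clca1 from 5053 to 161 (log2 -4.97), Fcgbp from 4002 to 155 (log2 -4.68), and Slc26a3, the chloride and bicarbonate exchanger of the colonocyte brush border, from 533 to 32.7 (log2 -3.99). Absorptive colonocyte genes had 16 of 20 lower and 1 higher (median -1.80) and goblet genes 11 of 16 lower and 1 higher (median -1.61), both below all random lists. Over the 11 alternatives the goblet median lay between -2.06 and -0.72, below the random range each time. In the goblet list Creb3l1, a transcription factor of secretory cells, fell by 2.40. Xenobiotic metabolism genes had 8 of 11 lower (median -1.86, below all random lists), with Cyp2c55 at -3.41, and enteroendocrine genes 5 of 8 lower (median -1.18, percentile 0.36), with the granins Chga at -2.34 and Chgb at -2.72. General epithelial genes had 2 of 12 lower and 1 higher (median -0.39), inside the random range, with Cdx2, an intestinal transcription factor, at -1.85 and Cldn4 at 4.19.

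Wnt target genes had 13 of 20 higher and none lower at W11 (median 2.03, above all random lists), with Wif1 at 420 CPM (log2 7.61), Apcdd1 at 6.05 and Dkk2, another secreted Wnt modulator, rising from 0.798 to 62.8 CPM (log2 5.15). Matrix remodelling genes (median 2.56, 6 of 10 higher, above all random lists) included Mmp7 at 293 CPM, a ratio of 4044 with a counting interval of 725 to 159747. Also above all random lists, neutrophil genes (median 2.60, 7 of 9 higher) included S100a9 at 6.29, cytokines (median 1.24, 10 of 15 higher and 1 lower) included Cxcl2 at 3.26, and mast cell genes (median 2.78, or 3.10 at the bounds, 6 of 8 higher and 1 lower) included Mcpt1 at 4.01. Mt4, a metallothionein, was at 0 at W0 and 327 CPM at W11, at least 1502-fold higher. Pnliprp1, a pancreatic lipase-related protein, rose from 2.69 to 532 CPM (log2 7.18) and Saa3 from 2.03 to 458 CPM (log2 7.24). Above random lists, squamous epithelium genes all rose (6 of 6, median 1.60, or 2.18 at the bounds), with Krt14 at 3.54, and hemoglobin genes all rose (4 of 4, median 1.51), with Hbb-bs at 2.12, where reads can be shared between copies. Without the length trend the hemoglobin median was 0.79, inside the random range. T cell genes had 3 of 12 higher and 1 lower, with a median of 0.47 inside the random range, with Zap70, a T cell receptor kinase, at 2.97 and Cd8a at -1.40. The immune checkpoint list had 1 of 8 higher and a median of 0.04, inside the random range, with Pdcd1, the gene of PD-1, at 1.60. That list stood above random lists at W2 (median 0.56, percentile 99.01) and at W5 (median 0.73, percentile 98.75). Its W5 place was kept under 5 of the 7 settings chosen beforehand. Among clock genes, Per2 fell by 3.58, and the lists that peak with Dbp (median -1.16, 3 of 6 lower) and with Bmal1 (median -1.19, 3 of 4 lower) both stood below random lists, each under 6 of the 7 settings chosen beforehand. Against W2 the median of the Dbp list was -0.078, inside the random range, and that of the Bmal1 list was -1.16. Proliferation genes stood above (median 0.41, 4 of 23 higher), but their median was -0.23 against W2, inside the random range. Immediate early genes (median -1.37, 7 of 12 lower) and adipocyte genes (median -1.67, 4 of 5 lower) stood below, the latter at -1.05 and inside the random range against W2.

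At W11, 11 lists stood above and 8 below random lists. Folds at W11 followed gene length (Spearman rho across genes -0.38), with a median of 0.55 in the decile of shortest genes and -0.68 in that of the longest, and cytosolic ribosomal protein genes held 12.4% of counts at W11 against 4.75% at W0. Without the length trend the numbers of higher and lower genes were 1295 and 2212, and with a pseudocount of 5 they were 1034 and 1558.

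**Figure D3:**
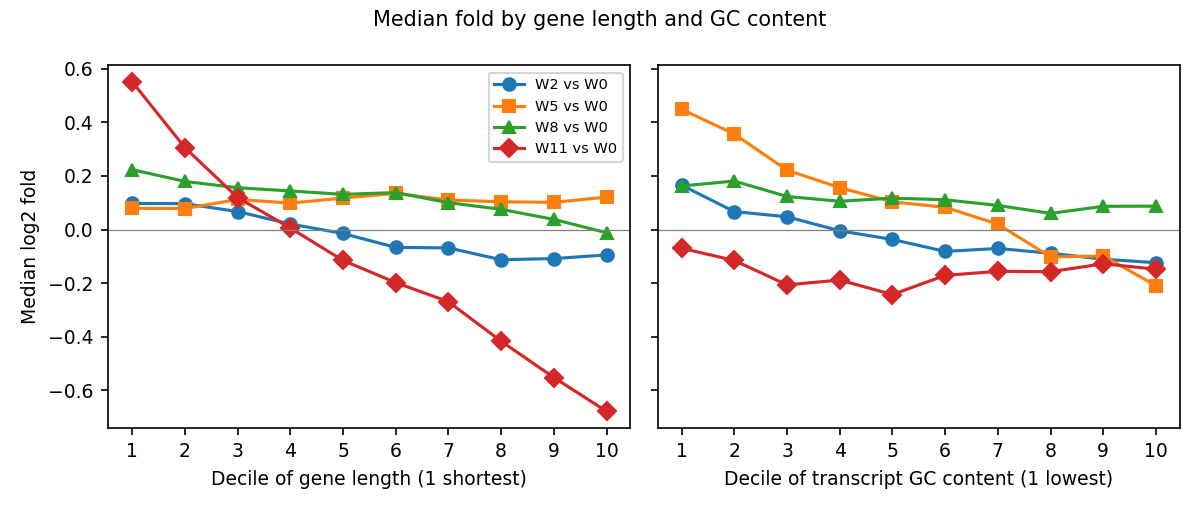
Median log2 fold against W0 in deciles of gene length (left) and of transcript GC content (right), with 1 line per comparison. The W11 line descends from 0.55 to -0.68 with length, and the W5 line from 0.45 to -0.21 with GC content.

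Genes that were changed at W5, W8 and W11 alike were led upward by Mmp7, Wif1, Saa3, Mmp10, Pnliprp1, Cxcl5, H19, Hp, Spock2 and Slc30a2. Spock2, an extracellular proteoglycan, rose from 10.1 CPM at W0 to 235 at W5, 933 at W8 and 721 at W11. Hp, haptoglobin, rose from 1.38 CPM to 53.3, 180 and 65.7, and Slc30a2, a zinc transporter, was at 24.0, 136 and 143 CPM against 3 counts at W0, with a W5 ratio of 110 and a counting interval of 37.5 to 536. Downward they were led by Sstr1, Naaladl1, Car4, Selenbp2, Slc37a2, Ankrd40cl, Ybx2, Tgm3, Fcgbp and Atp12a. Tgm3, a transglutaminase, fell from 2542 CPM to 812, 363 and 159, Slc37a2, a sugar phosphate transporter, from 208 CPM to 59.5, 20.3 and 11.2, and Atp12a, the colonic proton and potassium pump, from 192 CPM to 61.3, 54.1 and 21.1. In all, 378 genes were higher and 101 lower at each of the 3 time points. Shuffling the 5 values of each gene gave 269 higher genes on average (at most 303) and 170 lower (at most 211), so the higher count lay above the shuffled counts and the lower count below them. Shuffling keeps the spread of each gene's values, real differences between libraries included. Neither comparison with the shuffled counts therefore measures chance. Independent lists would give 8.58 and 1.79, and unchanged libraries with counting error alone gave 0.0500 and 0, and the 3 comparisons share the W0 library. Of these genes, 265 higher and 26 lower ones also met the criterion against W2. With a pseudocount of 5 the counts were 161 and 58. Leaving W5 out gave 727 higher and 452 lower genes.

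Folds at W8 and W11 were correlated across genes (r = 0.77, covariance 0.615). Shuffled values, which share W0 in the same way, gave r = 0.50 and a covariance of 0.330. Unchanged libraries with counting error alone gave r = 0.50 too, with a covariance of 0.0116. An r near 0.50 thus arises from sharing W0 alone and says little about the likeness of time points. The pairing of W8 against W0 with W11 against W2, which shares no library, gave r = 0.69. For W5 and W11 the correlation was 0.47, and 0.39 without a shared library. For W5 and W8 it was 0.66, and 0.37 without a shared library.

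**Figure D4:**
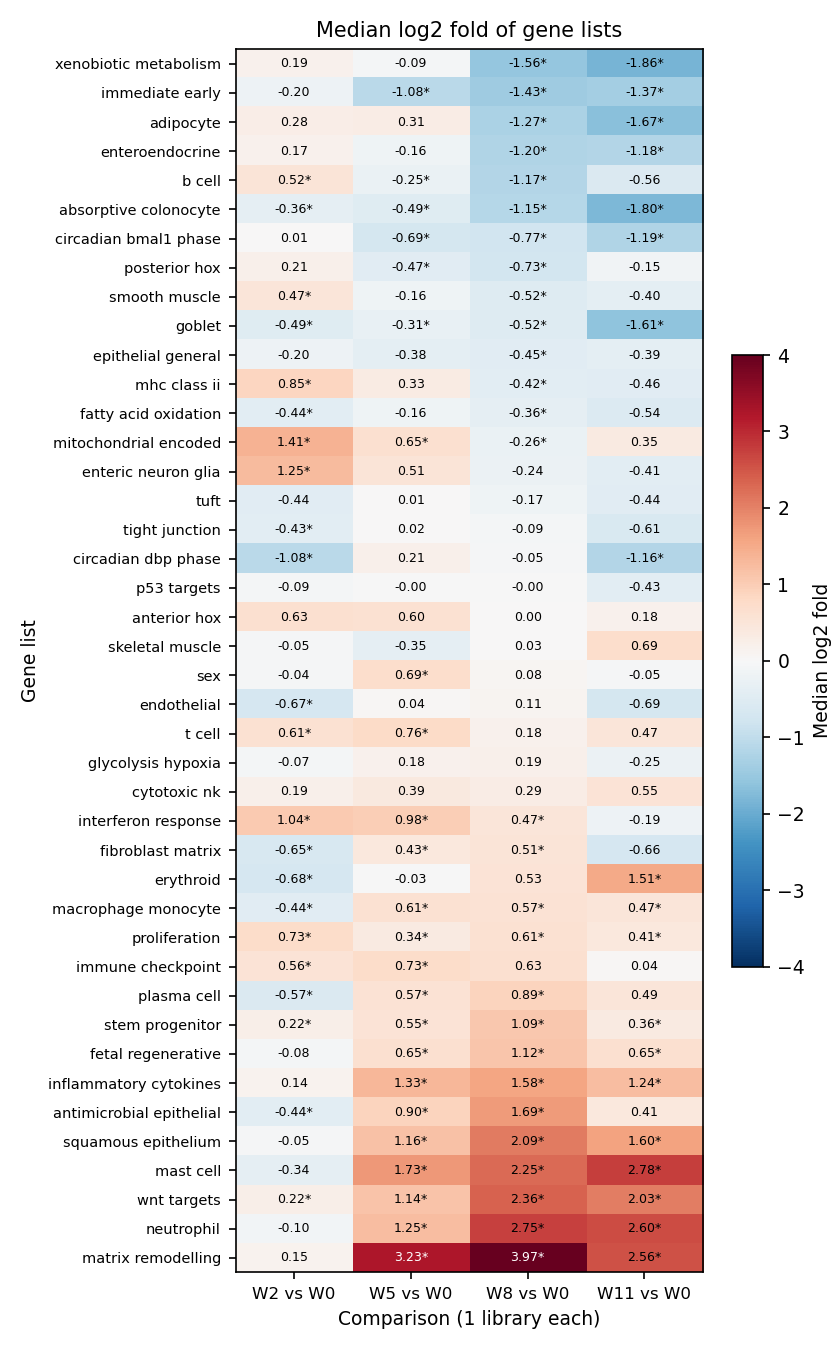
Median log2 fold against W0 of the 42 gene lists with at least 3 measured members (lines) in each comparison (columns), from 1 library per time point. A star marks a median outside the central 95% of 10000 random lists matched on expression. Matrix remodelling is highest at W8 (3.97) and xenobiotic metabolism lowest at W11 (-1.86).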

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

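All tests of explanations in this part were chosen after the results were seen. Of the lists fixed beforehand, 9 stood above random lists at some time points and below them at others, and the differences between time points were not tested. The antimicrobial list stood above at W5 and W8 and below at W2, with medians 2.13 apart at most. B cell genes stood above at W2 and below at W5 and W8, 1.69 apart, and the W5 median was 0.15 with RPKM. Hemoglobin genes stood above at W11 and below at W2, 2.19 apart, but the W2 place was kept under only 4 of 6 settings chosen beforehand and 6 of 9 in all, and the W11 place under 10 of 11. Fibroblast and matrix genes stood above at W5 and W8 and below at W2, 1.16 apart. Macrophage genes stood above at W5, W8 and W11 and below at W2, 1.05 apart, and the W11 place was kept under 9 of 11 settings, with a median of 0.048 without the length trend. MHC class II genes stood above at W2 and below at W8, 1.27 apart, and the W8 place was kept under 5 of 7 settings chosen beforehand and 6 of 11 in all. The mitochondrial-encoded list stood above at W2 and W5 and below at W8, 1.67 apart, and its W5 and W8 places were kept under 8 and 10 of 11 settings. For all 22 mitochondrial-encoded genes tested the W8 median was -0.037, inside the random range, and the W11 median was 0.53, above it, or -0.12 and inside it without the length trend. Plasma cell genes stood above at W5 and W8 and below at W2, 1.46 apart. Smooth muscle genes stood above at W2 and below at W8, 0.99 apart.

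Zg16 fell by 3.71 on the log2 scale at W11. A lower share of epithelial cells as the whole cause is argued against by the 12 general epithelial genes, of which none fell as far (lowest fold -1.85 in Cdx2, median -0.39). Scaling or the gene length trend is argued against as well, since median-of-ratios scaling gave -3.48 and removing the length trend gave -4.20. The smallest fall over all 11 alternatives was -3.20, with W2 as the baseline. A loss of goblet cells stays open at W11: the other 15 goblet genes had a median of -1.55 (SD 1.67), 2 of them fell as far, and Spink4, chosen after its value was seen, rose by 1.60, a spread too wide to decide. Only W11 was weighed. At W8 Zg16 (-2.60) was the lowest of the 16 goblet genes, whose median was -0.52. At W5 the lowest goblet fold (-1.64) was under that of Zg16 (-1.53). Against W2 the goblet median was 0.46 at W5 and 0.20 at W8, where Zg16 was at -1.03 and -2.09. Zg16 thus fell against W2 at these weeks without a fall of the goblet median. That baseline was added after seeing the data, and goblet genes were low in the W2 library itself (median -0.49 against W0, percentile 0.06). Against W0 the goblet list stood below random lists at W5 (median -0.31) and W8. Whether goblet genes lay below their baseline at these weeks thus depends on the baseline. At W11 a change of Zg16 within goblet cells and the treatment itself cannot be told apart from a loss of goblet cells, and with 1 library per time point neither can a difference between animals.

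Longer genes had lower folds at W11 (Spearman rho -0.384). Reads from introns as the cause are argued against by the 1115 genes with 1 exon, where rho was -0.384 too. Without the cytosolic ribosomal protein genes rho was -0.381, so the trend was present among the other genes. These are only 76 of the 14720 genes tested, so leaving them out could hardly have changed rho. This value therefore cannot decide on them as a cause. The trend was present against each of the other 4 libraries, with a weakest rho of -0.353 and a strongest of -0.434, whereas the 6 pairs without W11 lay between -0.122 and 0.101. It was thus seen in the pairs with W11, and a length-dependent step such as RNA quality or selection cannot be told apart from a biological difference, because W11 has 1 library.

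Of the 52382 genes listed, 27511 were at 0 in all libraries. Among protein-coding genes whose exons lie wholly inside other annotated genes 88.1% were at 0 (1296 of 1471), against 23.0% of those that overlap no other gene (3221 of 14019). A counting step that left out reads in overlapping genes may thus account for many of the enclosed genes at 0, but not for those 3221. Leaving out reads only where exons overlap is argued against by the wholly enclosed genes that share no exon, of which 92.4% were at 0 (629 of 681). Of the list genes 33 were at 0, 27 of them wholly enclosed, among them Timp1, Dmbt1, Ccl2, Cxcl10 and Foxp3, chosen after their values were seen. Xist, also chosen after its value was seen, is enclosed too, so its 0 says nothing about the sex of the mice.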

How the results depend on the processing

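The settings with RPKM, trend removal, W2 as the baseline and fewer time points were chosen after seeing the data, and the cause of the changes was not tested except where named. No paired analysis was possible because each time point has 1 library, and no library could be left out within a time point. Depth limits the folds of genes at few counts, which have intervals or bounds. In simulated counts with counting error only, 87 of 100 changes of 3-fold were called at W5 and 92 at W2. A reversal is a change of sign, counted only for lists that stood apart and for named genes at least 2-fold different from W0. Other values that changed sign were counted as stayed or moved. Of the values compared for list medians, 1053 stayed, 62 moved and 3 reversed under the settings chosen beforehand, and 539, 65 and 10 under those added. For named genes these numbers were 4049, 630 and 1, and 1704, 811 and 11. The calls of lists outside the random range were kept in 93 of 93 under median-of-ratios scaling, 92 of 93 with no filter or rescaled totals, 91 of 93 under either pseudocount, 83 of 90 at a mean of at least 5 CPM, 57 of 71 against the mean of W0 and W2 (1 on the other side), 89 of 93 and 88 of 93 without the length or GC trend, 80 of 92 with RPKM and 52 of 71 against W2 (4 on the other side).

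By construction a larger pseudocount shrinks folds. With a pseudocount of 5, higher and lower genes numbered 169 and 324 at W2, 447 and 128 at W5, 652 and 277 at W8, 1034 and 1558 at W11, and 161 and 58 at all 3 later time points. With 0.1 they numbered 865 and 947 at W2, 443 were lower at W5, and 587 were higher at all 3. A mean of at least 5 CPM, which tests fewer genes, left 325 higher at W2. Median-of-ratios scaling gave 416 lower at W5, and the mean of W0 and W2 as the baseline gave 64 lower at all 3. With RPKM fewer genes pass the filter. The RPKM values also sum to only 128172 (W0) to 154621 (W11) per library, against 1000000 for CPM, so the same pseudocount of 1 shrinks folds more. With RPKM the counts were 153 and 282 at W2, 483 and 125 at W5, 477 and 228 at W8, 947 and 839 at W11, and 150 and 43 at all 3. Against W2, 657 genes were lower at W5, 177 were lower at all 3, and 11 lists stood below random lists at W5. W8 and W11 alone gave 727 higher and 452 lower genes.

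The log2 fold of Zg16 at W2 was -0.46 under both other scalings, -0.56 with RPKM, -0.65 without the length trend and -0.44 without the GC trend. At W5 it was -1.67 under median-of-ratios scaling, -1.57 rescaled, -1.28 against the mean of W0 and W2, -1.45 with RPKM, -1.45 without the length trend, -1.49 without the GC trend and -1.03 against W2. At W8 it was -2.72, -2.64 and -2.35 under the first 3 of these, -2.65 without the length trend and -2.09 against W2. At W11 it was -3.48 under median-of-ratios scaling, -3.46 against the mean of W0 and W2, -4.20 without the length trend and -3.20 against W2.

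The correlation of W0 with W11 across genes was 0.861 and 0.893 with pseudocounts of 0.1 and 5, 0.951 with no filter, 0.816 at a mean of at least 5 CPM, 0.885 under both other scalings and 0.846 with RPKM. That of the folds at W8 and W11 was 0.793 and 0.752, 0.737, 0.786, 0.771 under median-of-ratios scaling and 0.770 rescaled, 0.734 against the mean of W0 and W2, 0.751 with RPKM, 0.787 and 0.769 without the length or GC trend, and 0.758 against W2.

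Direction was compared for genes at the time points where the naming rule picked them, if at least 2-fold different from W0. Of these folds, the following changed direction against W2: Cd3d at W8 (-0.062), Cdc20 (-0.0091) and Ube2c (-0.10) at W11, Clca1 at W5 (0.48) and W8 (0.54), Fcgbp at W5 (0.36) and W8 (0.20), Iigp1 at W5 (-0.56) and W8 (-1.43), Trpm5 (0.15) and mt-Co2 (-0.64) at W5. Of the lists that stood apart, the medians that did so were fatty acid oxidation at W8 (0.073), fetal and regenerative at W5 (-0.026), goblet at W5 (0.46) and W8 (0.20), interferon response at W8 (-0.67), mitochondrial-encoded at W5 (-0.79), proliferation at W5 (-0.33) and W11 (-0.23) and stem cells at W11 (-0.074). Against the mean of W0 and W2 they were Iigp1 at W8 (-0.058), interferon response at W8 (-0.14), mitochondrial-encoded at W5 (-0.069) and proliferation at W5 (-0.036), and with RPKM the B cell list at W5 (0.15).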

Other observations

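The gene classes and the removal of the length trend in this part were chosen after the data were seen. Cytosolic ribosomal protein genes were above W0 at W11, with 69 of 76 higher and a median of 1.38, above all random lists. Nuclear genes of the respiratory chain had 29 of 90 higher at W11 (median 0.74) and proteasome genes 12 of 44 higher (median 0.63). Folds at W11 were lower in longer genes (Spearman rho -0.38, median 0.55 in the decile of shortest genes). With that trend taken away these classes had 45 of 76 higher (median 1.11), 8 of 90 higher and 1 lower (median 0.36) and 10 of 44 higher (median 0.48), in the same order, and each median lay above all random lists. At W5 ribosomal protein genes (median -0.23, 4 higher and 6 lower, percentile 0.36, or -0.18 and inside the random range without the length trend) and respiratory chain genes (median -0.16, 2 higher and 7 lower, percentile 0.10) stood below random lists, and proteasome genes above (median 0.26, 1 higher). At W8 the respiratory chain stood below (median -0.10, 1 higher and 2 lower, percentile 0.15), and ribosomal protein (median 0.21, 1 higher) and proteasome genes (median 0.45, 1 higher) above. At W2 the medians of ribosomal protein, respiratory chain and proteasome genes were 0.48, 0.53 and 0.38, above all random lists, with 8, 11 and 2 higher and 1 lower in the respiratory chain. Defensin genes, which have near-identical copies, had 10 of 10 higher at W8 (median 3.90) and 9 of 10 at W11 (median 2.42), and metallothioneins 3 of 4 at each (medians 3.39 and 4.56). Keratins had 9, 11 and 12 of 18 higher at W5, W8 and W11 (medians 0.91, 1.50 and 1.90), with 1 lower at W11. Without the length trend the W11 medians were 1.67 in defensin genes (8 of 10 higher) and 3.88 in metallothioneins (3 of 4 higher). For keratins it was 1.62 (11 of 18 higher and 3 lower). Genes higher in each library than in the one before it numbered 307 and genes lower in each numbered 337, with steps of any size. Of these, 205 and 275 were also at least 2-fold higher or lower at W11 than at W0. An independent random order of each gene's values would give 123. Genes vary together between single libraries, so counts above 123 can arise without a trend over time.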
